A study of Mus musculus with 8 samples.

How the data were processed

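Chromatin accessibility was measured by ATAC-seq, which counts the places where a transposase could cut nuclear DNA, in primary lung fibroblasts of the mouse. Per the labels, the 8 libraries came from 4 cGAS knockout (KO) mice and 4 wild-type (WT) mice, with 2 female and 2 male mice per genotype. The cultures were kept at 5% CO2 and 5% O2, per the labels' protocols. cGAS is the enzyme that senses DNA in the cytosol and starts the type I interferon response. Libraries are named below by genotype, sex label and replicate number (KO F1, WT M2).

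The submitters' processing notes name Trim Galore, Bowtie2, SAMtools, Picard, MACS2, bedtools and featureCounts and the genome build GRCm39. Per the file headers, the deposited table holds estimated counts from featureCounts 2.0.3, made over peaks and repeat annotations together from cleaned alignments of each library. Each read was reduced to its 5' end, both ends of a pair had to be aligned, and a read end that lay in several regions added an equal fraction to each, per the file headers. A retrotransposon inside a peak therefore shares its counts with that peak. Whether read positions were shifted for the transposase was not given in the sources used here, nor were the aligner's treatment of reads with several equal matches or the rules for merging peaks across libraries. Reads placed among near-identical repeat copies make single young copies uncertain, which is why counts were also summed over subfamilies. Coordinates are those of the table, in GRCm39.

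The table held 4835895 regions, of which 185268 were peaks, called open chromatin regions (OCRs) here, with a median length of 519 bp (201 to 5013), and 4650627 were repeats. Retrotransposons made up 2968871 of the repeats (684873 LINE, 1400160 SINE, 870063 LTR and 13775 Retroposon copies), and 61.98% of OCRs overlapped a repeat. Library totals ranged from 43.2 to 72.9 M counts, totals over OCRs from 28.0 to 55.3 M and totals over retrotransposons from 13.3 to 16.4 M.

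The estimated counts were rounded to whole numbers before every count model. The design, tests, named features and the first list of alternatives were fixed before the data were examined. OCRs were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit), with the sex label as a covariate, TMM factors over OCRs and filterByExpr, which kept all 185268 OCRs. Retrotransposon copies were tested in the same way with the whole table total as library size and TMM factors from OCRs and copies together, and filterByExpr kept 570571 of 2968871 copies. Counts summed over copies of a subfamily were tested for 831 of 871 subfamilies, those with a mean of at least 100 counts per library. P-values were adjusted by Benjamini-Hochberg within each family of tests, and the threshold was an adjusted p of 0.05. Shares of counts were compared by exact two-sided permutation tests over the 70 assignments of 4 against 4 libraries, in which the smallest possible p is 0.0286, and fold intervals were found by inverting that test at 95%. Shares of a group are given as mean ± SD. Values in CPM (counts scaled to the library size) were computed with the TMM-scaled library sizes of each fit, and log2 values used a prior count of 2.

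No OCR passed the threshold between genotypes in edgeR, so by the rule fixed beforehand the 5 OCRs with the lowest p in each direction are named with values only. The same rule named the 4 members with the lowest p of a fixed list of 24 subfamilies and the 5 subfamilies with the lowest p in each direction. The alternatives tried were DESeq2 1.42.0, limma 3.58.1 voom with sample weights, other scaling factors, other count filters, no sex covariate, a replicate block, autosomes only, copies outside OCRs, other denominators and leaving out each library. Fits with surrogate variables (sva 3.50.0) and with the repeat share as a covariate were added after seeing the data. Overlap of OCRs with retrotransposon families was tested by the Mantel-Haenszel method within 10 length classes of OCRs.

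The tests were checked on simulated counts. With 200 changed OCRs among 9264, the OCR test recovered 4.5% of 1.5-fold, 28.4% of 2-fold and 84.8% of 4-fold changes. For retrotransposon copies (28529 simulated), it recovered 0% of 2-fold and 45.5% of 4-fold changes. For the 831 subfamilies, it recovered 19.4% of 1.2-fold, 82.1% of 1.5-fold and 97% of 2-fold changes. The permutation test gave p under 0.05 in 2.8% of 400 simulated null comparisons, and its 95% interval held the true shift in 95% of 100 simulated shifts. The only p under 0.05 that this test can give is 0.0286, so the first share checks the calculation alone. For the same reason the intervals are wider than 95% requires.

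No genome or annotation in GRCm39 was used here. The correction for GC content, the distance of OCRs to promoters, the lists of genes and of cell-type markers fixed beforehand, and the Cgas locus were therefore not analysed here, and no OCR is assigned to a gene. The knockout itself was not checked in the counts.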

Results

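The series compared chromatin accessibility in lung fibroblasts of cGAS KO and WT mice, and its title raises chromatin organization and LINE1 derepression as the questions. The table totals were 62.7, 59.0, 72.9 and 43.2 M counts for KO F1, KO F2, KO M1 and KO M2, and 54.1, 63.3, 66.4 and 70.5 M for WT F1, WT F2, WT M1 and WT M2. A median OCR held 101.9 counts per library. Pearson's r of log2 CPM between pairs of libraries, across OCRs (which are not independent replicates), ranged from 0.865 to 0.971. The median r was 0.923 for pairs within KO, 0.927 for pairs within WT and 0.92 for pairs across genotypes.

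The leading component of the OCRs did not separate the genotypes or the sex labels. PC1 held 45.7% of the variance, and KO F1, KO M1, WT F1 and WT M2 lay on its negative side, with the other 4 libraries on the positive side. PC2 held 26.6%, and all 4 KO libraries (-144.4 to -41.6) lay below all 4 WT libraries (-9.4 to 162.2). WT F1 was the WT library nearest to the KO libraries, and this separation on PC2 was not tested.

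**Figure D1:**
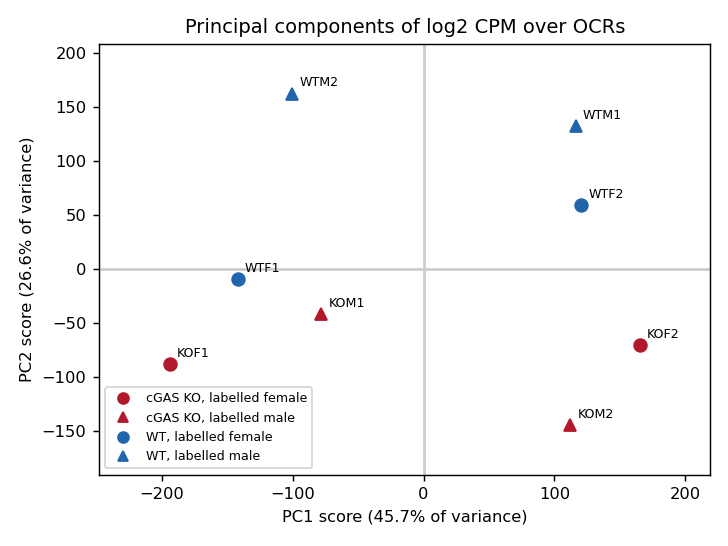
Scores of the 8 libraries on the first and second principal components of log2 CPM over 185268 OCRs, with the percent of variance on each axis, colour for genotype and shape for the sex label. PC1 (45.7%) places KO and WT libraries on both sides of 0.

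The library labelled cGAS KO F2 had counts in a part of the Y chromosome that was almost empty in the other 3 female-labelled libraries. Its 15 OCRs in the first 2 Mb of Y summed to 25.0 CPM (1028 counts), against at most 0.06 CPM in the other 3 female-labelled libraries and 35.9 ± 5.2 CPM (SD, n = 4) in the male-labelled ones. Its X chromosome L1 counts were 8.06 per 100 autosomal L1 counts, against 7.13 ± 0.65 in the 4 male-labelled and 10.68 ± 0.70 in the other 3 female-labelled libraries. Each male-labelled library had counts in these 15 OCRs (31.2 to 43.3 CPM). The limit of 2 Mb was chosen after the counts were seen, because Y OCRs further along were counted in all libraries. The 27 OCRs from 90 Mb held most Y counts. Over all 87 Y OCRs the library labelled KO F2 had 268 CPM, the male-labelled ones 235 to 350.5 and the other 3 female-labelled ones 364 to 477, so the order over the whole chromosome was the reverse. This reversal came from the 27 OCRs from 90 Mb, with 157 to 245 CPM in male-labelled and 319 to 436 in the other 3 female-labelled libraries. From 2 to 90 Mb the male-labelled libraries had 46.7 to 62.5 CPM and the other 3 female-labelled ones 39.7 to 45.2. Every test below keeps the sex as labelled.

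**Figure D2:**
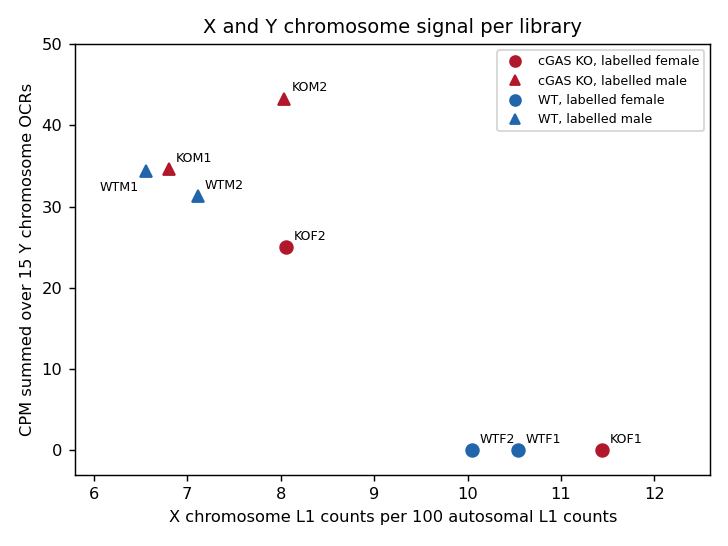
CPM summed over 15 Y chromosome OCRs against X chromosome L1 counts per 100 autosomal L1 counts, for the 8 libraries, with colour for genotype and shape for the sex label. The library labelled KO F2 lies at 8.06 on the X axis measure and 25.0 CPM in these OCRs, apart from the other 3 female-labelled libraries.

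Between genotypes, the OCRs with the lowest p had moderate to large differences, and none passed the threshold in edgeR, while all 10 named here passed in DESeq2. Of those with higher values in KO, the OCR at 5:76093910-76094791 had 9.13 ± 1.5 CPM in KO and 4.04 ± 0.83 in WT (SD, n = 4 each), a 2.28-fold difference (edgeR adjusted p = 0.323). The OCR at 2:45151850-45152443 had 4.38 ± 1.38 against 1.31 ± 0.34 CPM (3.37-fold), and the OCR at 15:9571793-9572332 had 2.57 ± 0.63 against 0.776 ± 0.185 CPM (3.35-fold). The OCR at 15:96641118-96641641 had 7.47 ± 1.37 against 3.50 ± 0.44 CPM (2.13-fold), and the OCR at 14:30887970-30888844 had 21.9 ± 2.2 against 13.5 ± 0.72 CPM (1.63-fold). Of those with lower values in KO, the OCR at 2:147424691-147425284 had 0.450 ± 0.137 against 1.60 ± 0.26 CPM (3.55-fold higher in WT), and the OCR at 10:86261428-86262247 had 1.55 ± 0.38 against 5.18 ± 2.41 CPM (3.19-fold). The OCR at 12:26406095-26406947 had 1.83 ± 0.36 against 3.99 ± 0.88 CPM (2.17-fold). The OCR at 2:168452682-168453422 had 4.81 ± 1.36 against 9.52 ± 2.85 CPM (1.96-fold), and the OCR at 11:94844175-94845799 had 23.1 ± 4.7 against 38.5 ± 4.9 CPM (1.67-fold). In each of these 10 OCRs all 4 KO libraries lay on one side of all 4 WT libraries, and the adjusted p of each was 0.323. They were picked by the lowest p among 185268 OCRs. That choice favours separated groups, inflated folds and DESeq2 calls on the same counts, so these are no separate evidence. The OCRs at 5:76093910-76094791, 15:96641118-96641641, 2:45151850-45152443, 11:94844175-94845799 and 12:26406095-26406947 overlap a repeat and can share counts with it.

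**Figure D3:**
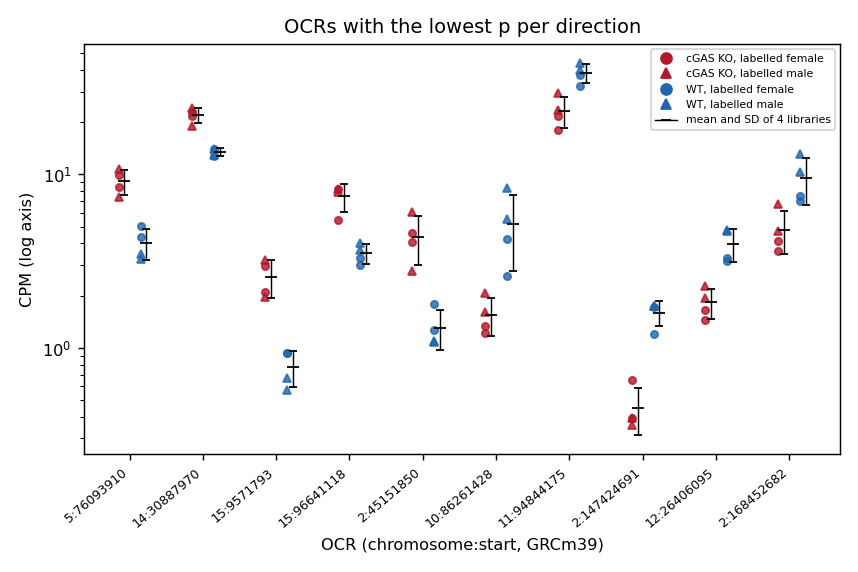
CPM of the 10 OCRs with the lowest p (5 per direction) on a log axis, each point 1 library and each bar the mean and SD of 4 libraries, with colour for genotype and shape for the sex label. In all 10 the KO and WT libraries do not overlap, from 0.450 against 1.60 CPM at chromosome 2 position 147424691 to 23.1 against 38.5 CPM at chromosome 11 position 94844175. The choice by lowest p favours such separation.

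With edgeR, 0 of 185268 OCRs passed an adjusted p of 0.05, and 18296 (9.9%) had an unadjusted p under 0.05. DESeq2 called 2739 OCRs, 2306 higher and 433 lower in KO, all with an unadjusted edgeR p under 0.05. limma voom with sample weights called 0, with 28283 at an unadjusted p under 0.05. The groups did not overlap in 11082 OCRs (5.98%), where the average over all assignments of 4 against 4 libraries is 2.86%. OCRs vary together, so a single assignment can lie far from that average without a genotype effect. This share was not computed for other splits, so no conclusion is drawn from it. In a subset of 9264 OCRs, 923 had an unadjusted p under 0.05 between the genotypes, and 7 of the 35 splits of the libraries into groups of 4 (the genotypes included) gave at least as many, at most 3498. The edgeR 95% intervals excluded a 2-fold difference for 60.5% of OCRs and a 4-fold difference for 95.5%. With 1 surrogate variable in the edgeR model, an alternative added after seeing the data, 10787 OCRs passed, 7790 higher and 2997 lower in KO, at a median fold of 2.1. Of the OCRs called by DESeq2, 2733 were among them, and the named OCRs were called by both. This count fell to 0 without WT F2 and without WT M1, where the lowest adjusted p was 0.066 and 0.0864 and 30817 and 30028 OCRs had an unadjusted p under 0.05, against 38650 with all libraries. It fell to 2960 without WT M2 and to 3463 without KO M2, and was 20508 without WT F1. The estimate of the number of surrogate variables by sva (be method) was 1, so a fit with 2 goes beyond it. With 2 surrogate variables 0 OCRs passed, with 7954 at an unadjusted p under 0.05, and the named OCRs had an adjusted p of 1. In that fit, against the planned edgeR fit, log2 folds went from 1.19 to 0.56 at 5:76093910-76094791, from 1.75 to 0.99 at 2:45151850-45152443 and from 1.74 to 1.04 at 15:9571793-9572332. They went from -1.67 to -0.78 at 10:86261428-86262247, from -1.83 to -1.04 at 2:147424691-147425284 and from -0.97 to -0.53 at 2:168452682-168453422. The remaining named OCRs moved less, from 1.094 to 1.033 at 15:96641118-96641641 and from -0.74 to -0.705 at 11:94844175-94845799. At 12:26406095-26406947 the log2 fold went from -1.117 to -0.904, and at 14:30887970-30888844 from 0.704 to 0.553. How the second surrogate variable relates to genotype was not examined, so this fit does not decide whether the differences persist.

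The genotype difference was also compared between the sexes, and no OCR passed the interaction test (edgeR 0 called, 2867 at an unadjusted p under 0.05; DESeq2 0 called, 2568). Within female-labelled libraries edgeR called 0 OCRs (2497 at an unadjusted p under 0.05), and within male-labelled ones 0 (17403). These within-sex counts rest on 2 libraries per genotype and include the library labelled KO F2.

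Between the sex labels, edgeR called 0 OCRs (1845 at an unadjusted p under 0.05) and DESeq2 called 21, all lower in male-labelled libraries. Without the library labelled KO F2, edgeR called 15 OCRs. Of these, 7 lay on Y and were higher in male-labelled libraries, 8 lay on X and were lower, and 0 were autosomal.

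L1, the LINE family that still holds mobile copies in the mouse, took shares of retrotransposon counts that differed between genotypes by less than the spread between libraries. L1 held 30.1% ± 3.2 of retrotransposon counts in KO and 29.0% ± 3.9 in WT (SD, n = 4 each), a fold of 1.04 with a 95% interval of 0.771 to 1.34 (exact permutation p = 0.629, adjusted p = 1). The young L1 class, whose names start with L1Md, held 11.6% ± 2.4 in KO and 10.8% ± 2.5 in WT, a fold of 1.08 (0.610 to 1.76; exact permutation p = 0.600). L1 copies of at least 5 kb held 5.87% ± 1.34 and 5.39% ± 1.48 (exact permutation p = 0.600). The L1 difference of 1.04 percentage points turned to -0.518 without WT M1, and was 0.140 without KO F1, 0.252 without KO M2, 2.39 without KO M1 and 2.65 without WT F1. Among SINE families, Alu (B1) held 10.5% ± 0.69 in KO and 10.5% ± 0.51 in WT, and B2 held 10.4% ± 1.1 and 10.8% ± 1.6. Among LTR families, ERVK held 11.4% ± 0.53 and 11.1% ± 0.39, ERVL 4.08% ± 0.26 and 4.29% ± 0.32, and ERVL-MaLR 14.8% ± 0.54 and 15.1% ± 0.82. All 10 families tested had an adjusted p of 1 in the exact permutation test.

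Retrotransposons as a whole took 26.1% ± 4.1 of the table's counts in KO and 24.5% ± 4.4 in WT, a fold of 1.07 (0.687 to 1.51; exact permutation p = 0.514). The difference of 1.57 percentage points was 0.003 without KO M2, 0.195 without WT M1 and 0.719 without WT M2, and 3.32 without KO M1 and 3.53 without WT F1. The libraries of 1 genotype differed more from each other than the genotypes did, from 20.8% (KO M1) to 30.8% (KO M2) and from 20.4% (WT M1) to 30.4% (WT F1). Across the 8 libraries, the L1 share of retrotransposon counts outside OCRs was higher where more of the table lay in repeats outside OCRs. Pearson's r was 0.823 (exact permutation p = 0.0145, adjusted p = 0.109 over 15 relations) and Spearman's rho 0.738 (exact permutation p = 0.0458). Without WT M1 and KO M2, the libraries farthest from the median on the x axis, r was 0.777. The relation did not pass the adjustment and was not among the tests fixed beforehand. L1 counts are part of both measures, so these are coupled to some degree by construction.

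**Figure D4:**
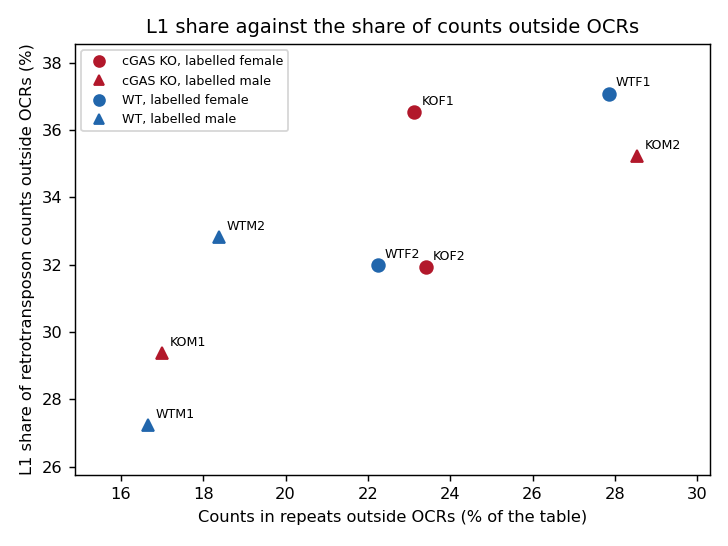
L1 share of retrotransposon counts outside OCRs (percent) against the share of the table's counts in repeats outside OCRs (percent), for the 8 libraries, with colour for genotype and shape for the sex label. KO and WT libraries lie along the same range, with r of 0.823 (adjusted p = 0.109, exact permutation test). L1 counts are part of both measures.

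None of the subfamilies passed the threshold (edgeR 0 of 831, 15 at an unadjusted p under 0.05; DESeq2 0, 29; limma voom with sample weights 0, 25). Among the 25 young L1Md subfamilies, all 25 fold changes lay above 0 with a median log2 of 0.195, and 0 had an unadjusted p under 0.05. L1MdTf_I had 966 ± 348 CPM in KO and 824 ± 297 in WT, a fold of 1.21 (95% interval 0.702 to 2.07; edgeR adjusted p = 0.875). L1MdA_I had 1480 ± 536 and 1266 ± 437 CPM, a fold of 1.2 (0.702 to 2.05), and L1MdGf_I 805 ± 273 and 693 ± 224 CPM, a fold of 1.19 (0.721 to 1.96). The L1Md median was 0.143 with scaling on retrotransposons alone and 0.299 with scaling on OCRs. It turned to -0.098 without KO M2 (0 of 25 above 0) and to -0.017 with limma voom sample weights (7 of 25), and was 0.043 without WT M1.

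**Figure D5:**
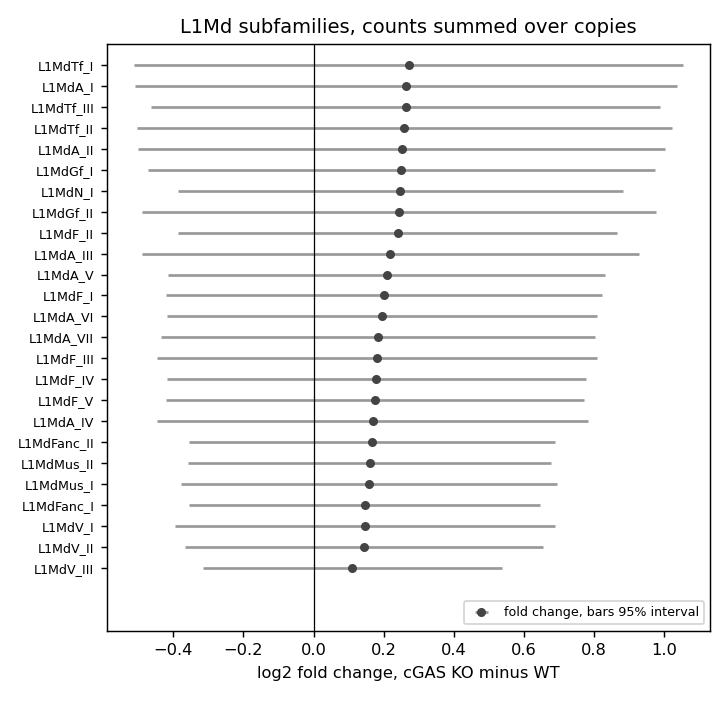
Log2 fold change of KO over WT for the 25 L1Md subfamilies (counts summed over copies), with bars for the 95% interval of the edgeR fit over 4 KO and 4 WT libraries. All 25 points lie above 0 with the joint scaling, and all 25 intervals include 0; without KO M2 none of the 25 lies above 0, and with limma voom sample weights 7 do.

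Of the fixed list of 24 subfamilies, 0 passed adjusted over all 831 and 0 adjusted over the list alone. The 4 with the lowest p were RLTR6_Mm (209 ± 37 CPM in KO, 189 ± 36 in WT, fold 1.10), B1_Mm (1840 ± 205 and 1716 ± 126 CPM, 1.07), MMVL30-int (400 ± 72 and 370 ± 34 CPM, 1.08) and MERVL-int (872 ± 206 and 973 ± 119 CPM, 0.896). The subfamilies with the lowest p above 0 were RLTR30D2_MM (fold 1.14), MER54A (1.12), X7A_LINE (1.22), RLTR50A (1.29) and RMER16_Mm (1.35; 35.7 ± 7.3 against 26.7 ± 5.0 CPM). Those below 0 were MER68C (0.760; 1.84 ± 0.14 against 2.42 ± 0.11 CPM), LTR86C (0.847), L1M8 (0.868), X13_LINE (0.786) and MER68B (0.908). All 14 had an adjusted p of 0.875 by edgeR. On the log2 scale, RLTR6_Mm went from 0.14 to 0.03 without WT M2 and 0.34 on copies outside OCRs, B1_Mm from 0.10 to -0.006 without KO M2, and MMVL30-int from 0.11 to 0.01 without KO F1. MERVL-int went from -0.16 to -0.02 without KO M1 and -0.36 without KO M2, and X7A_LINE from 0.29 to 0.03 on copies outside OCRs. Without KO M2, RMER16_Mm went from 0.43 to 0.24 and RLTR50A from 0.37 to 0.24. On copies outside OCRs, LTR86C went from -0.24 to -0.39 and MER54A from 0.16 to 0.11, and with scaling on OCRs MER68B went from -0.14 to -0.07. Fold changes of 622 of the 831 subfamilies lay above 0 with the joint scaling, 451 with scaling on retrotransposons alone and 763 with scaling on OCRs, so this balance depended on the scaling.

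At the level of single retrotransposon copies, edgeR called 0 of 570571 (20228 at an unadjusted p under 0.05), limma voom with sample weights 0 (20865) and DESeq2 64 of the 50653 copies left by its own filter. Of these 64, 62 were higher and 2 lower in KO. The 62 higher copies comprised 42 LTR, 17 LINE and 3 SINE copies, with 26 ERVL-MaLR and 13 L1 copies among them, and 0 were young L1 copies. Among the 50653 copies, 6683 were ERVL-MaLR and 13061 young L1. Of the 62, 33 overlapped an OCR and so share counts with it. The tested copies had a median of 11 counts per library, and in simulated copies edgeR recovered 0% of 2-fold differences, so differences of that size in single copies are not excluded.

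The concentration of OCR counts differed between genotypes by less than the spread between libraries. The 10% of OCRs with the highest mean CPM held 47.3% ± 1.4 of OCR counts in KO and 47.7% ± 2.2 in WT (SD, n = 4 each; exact permutation p = 0.743). The difference of -0.39 percentage points turned to 0.086 without KO F1, 0.096 without WT F2 and 0.356 without WT M1. The median r of a library with the others of its genotype was 0.920 ± 0.019 in KO and 0.928 ± 0.011 in WT (exact permutation p = 0.686). The shares of OCR counts per chromosome all had an adjusted p of 1 in the exact permutation test. Chromosome 18 held 3.20% ± 0.06 in KO and 3.26% ± 0.02 in WT, and chromosome 6 5.21% ± 0.03 and 5.26% ± 0.04 (exact permutation p = 0.143 for each). Satellite repeats, which make up much of the heterochromatin around mouse centromeres, held 0.621% ± 0.143 of the table in KO and 0.592% ± 0.244 in WT. DNA transposons held 0.977% ± 0.052 and 0.959% ± 0.071, and the adjusted p of each repeat class was 1 (exact permutation test).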

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

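The surrogate variable fits, the repeat share covariates, the counts over other splits and the tests of X and Y levels were chosen after the results were seen, while DESeq2, limma voom sample weights, autosomal copies and leaving out a library from the planned fits were planned. Of the tests in this part, bounds were set before their values were computed for the simulation without a genotype effect, the surrogate variable fit with the joint scaling and the covariate made from repeats other than L1.

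Over all 87 Y OCRs the library labelled cGAS KO F2 had 267.71 CPM, inside the male-labelled 235.03 to 350.5 and below the other 3 female-labelled libraries (364.45 to 477.11). The 27 OCRs from 90 Mb set that order. Over 15 OCRs in the first 2 Mb of Y, a limit chosen after the counts were seen, it had 25.03 CPM against at most 0.06 in the other 3 female-labelled libraries. Within these 15 OCRs, cells of a female mouse only are ruled out by that value, and an exchange of labels with a male-labelled library of this series is ruled out because the lowest of these had 31.24 CPM. Cells of a male mouse under a wrong label would fit, since both this Y level and the X level of 8.06 lay inside the 95% prediction ranges of the male-labelled libraries (17.5 to 54.3 CPM and 4.82 to 9.44). A mixture of male and female cells cannot be told apart from that, because the Y level was 69.8% of the male mean and the range from 4 libraries is wide. No biological explanation was tested.

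The number of OCRs called between genotypes ran from 0 with edgeR to 2739 with DESeq2 and 10787 with 1 surrogate variable, the last going to 0 without WT F2 or WT M1 (lowest adjusted p 0.066 and 0.0864), 2960 without WT M2, 3463 without KO M2 and 20508 without WT F1. Other splits of the 8 libraries into groups of 4 were compared over a subset of 9264 OCRs. In the surrogate variable fit 3 of the 35 splits, the genotypes included, gave at least as many calls (463 for the genotypes, at most 3507 in another split). In DESeq2 3 of 35, again with the genotypes included, did so (122, at most 2333), so chance cannot be excluded for either. One of these, KO F1, KO M1, KO M2 and WT F1 against the rest, holds 3 of the 4 KO libraries. It gave 1463 calls in the surrogate variable fit and 583 in DESeq2, and is not free of genotype. The surrogate variable fitted with the genotypes had the sign of PC1 in all 8 libraries. The split with most calls in both, KO F1, KO M1, WT F1 and WT M2 against the rest, calls several times as many OCRs. It follows the sign of PC1, so many calls are built into it, and it is neither the genotype nor the sex label. It matches replicate number 1 against 2 except that WT M1 and WT M2 are crossed. What the libraries share along it was not tested. With the joint scaling 10507 OCRs passed in the surrogate variable fit, but this does not decide whether different totals inside OCRs play a part. That scaling moved the median log2 fold over all OCRs only from -0.00466 to -0.0635. The called OCRs had a median absolute log2 fold of 1.07, so a uniform shift of that size could hardly remove them. False calls by the surrogate variable fit cannot be told apart. In 5 simulations with a hidden factor and no genotype effect it called 0 OCRs, which met the bound set beforehand. That bound was wrong as an exclusion because the simulated factor is simpler than the splits show these libraries to be. A genotype effect on part of the OCRs remains a hypothesis.

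The 25 L1Md subfamilies all had fold changes above 0 (median log2 0.195), the direction that the series title raises, which turned to -0.098 without KO M2 and to -0.017 with limma voom sample weights. Chance cannot be excluded, since 22 of the 35 splits, the genotypes included, gave a median at least as far from 0 (at most 0.61). All 25 had the same sign in 33 of the 35. The median kept a value of 0.181 on autosomal copies. X chromosome L1 counts outside OCRs were only 6.56 to 11.44 per 100 autosomal ones in the 8 libraries. Leaving them out could therefore hardly change the median, so this test could not have come out otherwise. It shows only that counts on X themselves add little to the median. It fell to 0.01 (21 of 25 above 0) with the repeat share of the table as a covariate, a share that holds L1 itself, and to 0.027 (24 of 25) with the share of repeats other than L1 outside OCRs. A candidate explanation is therefore that libraries with more counts outside OCRs gain L1 counts in either genotype, and an effect of genotype on both was not separated from it.

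The remaining values are given without explanation. In groups of 4, a library was noted when its gap to the nearest other exceeded Dixon's 95% critical share of the group's range, which chance gives in about 1 of 20 groups, and this held in 6 of 130 groups including the Y value above. The library labelled KO F2 had 5.425 CPM at the OCR 15:96641118-96641641, against 7.892 to 8.294 in the other KO libraries. It had 0.6539 CPM at the OCR 2:147424691-147425284, against 0.3587 to 0.3961. At that OCR WT F1 had 1.205 CPM, against 1.710 to 1.742 in the other WT libraries. KO M1 had 6.112% of its OCR counts on chromosome 5, against 6.080% to 6.082% in the other KO libraries, and KO F1 had 6.411% on chromosome 7, against 6.553% to 6.557%.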

How the results depend on the processing

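The surrogate variable and repeat share fits here were chosen after seeing the data, as were all the tests of other splits. Main results stayed the same in 102 of 116 alternatives. For counts of calls this means an equal count or one of similar size, whatever the direction. For shares it means the same direction and side of the threshold. Most of the unchanged counts were 0 calls that stayed at 0, which says nothing about direction. The named OCRs kept their direction and side of the threshold in 179 of 199 alternatives, and the named subfamilies in 292 of 293. The other 20 of the named OCRs' alternatives were past the threshold (DESeq2 or 1 surrogate variable).

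OCRs called between genotypes were 0 in the other edgeR settings and with limma voom sample weights (7954 to 28283 at an unadjusted p under 0.05), 2739 with DESeq2 and 10787 with 1 surrogate variable, which without 1 library ranged from 0 (without WT F2, without WT M1; lowest adjusted p 0.066 and 0.0864) to 20508 (without WT F1), with 2960 without WT M2 and 3463 without KO M2. OCRs called between sex labels were 21 with DESeq2, and 0 to 15 without 1 library (15 without KO F2). DESeq2 called 64 retrotransposon copies, and the subfamily count was 0 in all fits run. The cause of the gap between tools was not tested. Other splits called at most 1918 of a subset of 9264 OCRs (2985 in the model of sex), 52 of a subset of 14265 copies and 4 of 831 subfamilies with edgeR. Since the real labels gave 0 calls in each, all 35 splits count as at least as large and the comparison is uninformative.

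Without 1 library, the difference in retrotransposon share ran from 0.003 (without KO M2) to 3.53 points (without WT F1), the L1 difference from -0.5175 (without WT M1) to 2.652 points, the difference in the top 10% of OCRs from -1.244 to 0.3559 (0.08552 without KO F1, 0.09581 without WT F2, 0.3559 without WT M1), the log2 fold of B1_Mm from -0.006 (without KO M2) to 0.156, of MMVL30-int from 0.013 to 0.194, of RLTR6_Mm from 0.026 to 0.226 and of MERVL-int from -0.356 to -0.017, and the L1Md median from -0.098 (without KO M2) to 0.349 (without WT F1). Fewer libraries alone can move these values.

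With the replicate block the calls stayed at 0 (23009 OCRs, 27562 copies and 28 subfamilies at an unadjusted p under 0.05). Sex label and replicate number together paired only the female-labelled libraries. Deviations of KO and WT libraries with the same label and number correlated at 0.59, 0.61, -0.29 and -0.45 for F1, F2, M1 and M2. KO M1 correlated best with WT M2 (0.38), and KO M2 with WT F2 (0.5), which has the same number and another sex label.

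The GC offset, alone and with the block, the promoter context, the promoter share and the gene lists with their alternatives were not run. The filter on a total of 10 counts removed no OCR. Tested single copies had a median of 11 counts per library; the effect of depth itself was not tested.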

Other observations

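The tests in this part were chosen after the results were seen, except the test for young L1 copies, whose bound was set before its value was computed.

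OCRs called with 1 surrogate variable differed from the other OCRs in the retrotransposons they overlap, within classes of equal OCR length. Of the 7790 higher in KO, 12.5% overlapped an ERVL-MaLR copy, more than among the 174481 not called (odds ratio 1.27, 95% interval 1.19 to 1.36, adjusted p = 2.61e-10 over 44 tests). MIR copies also lay under more of them (odds ratio 1.2, 1.08 to 1.33, adjusted p = 0.00362), and B2 (0.791), ERVK (0.838) and ERV1 (0.646) copies under fewer, with adjusted p of 2.16e-05, 0.00613 and 0.00036. Of the 2997 lower in KO, 5.14% overlapped an L1 copy, against 7.93% (odds ratio 0.622, 0.528 to 0.733, adjusted p = 1.91e-07). B2 (0.612), Alu (0.749) and B4 (0.771) copies also lay under fewer of them. Among OCRs called by DESeq2, B2 copies lay under fewer of both the higher (0.716) and the lower (0.373) ones, and ERVK copies under fewer of the higher ones (0.667). Alu (0.492) and B4 (0.555) copies lay under fewer of the lower ones. The other differences did not pass in DESeq2: for the higher OCRs ERVL-MaLR had an odds ratio of 1.14 (0.999 to 1.31, adjusted p = 0.125), MIR 1.22 (adjusted p = 0.104) and ERV1 0.771 (adjusted p = 0.317), and for the lower OCRs L1 had 0.637 (adjusted p = 0.102). The length classes did not equalize the counts of OCRs, on which the chance of being called depends. A difference in counts is therefore not separated from these results. OCRs are not independent of each other, counts are shared with overlapping copies, and the calls are those weighed above, for which other splits of the libraries gave as many. Those of the surrogate variable fit fell to 0 without WT F2 or WT M1 (lowest adjusted p 0.066 and 0.0864), and the DESeq2 calls were not repeated without single libraries.

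If loss of cGAS opened young L1 copies, these should lie under more of the OCRs higher in KO. Young L1 copies lay under 0.924% of them and 0.877% of OCRs not called, an odds ratio of 1.02 (0.806 to 1.30, adjusted p = 0.939), which met the bound set beforehand for no excess. Missing the threshold does not exclude an excess. The interval treats OCRs as independent and holds no variation between libraries, so an odds ratio above 1.30 is not excluded either.

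B2, a SINE family transcribed by RNA polymerase III, took 8.97% to 13.13% of retrotransposon counts outside OCRs per library, lowest in KO F1 (8.97%) and WT F1 (9.01%) and highest in WT M1 (13.13%). This share may follow the leading component of the OCRs, with a Pearson's r of 0.728 against PC1 (exact permutation p = 0.0388, adjusted p = 0.194 over 15 relations) and a Spearman's rho of 0.881 (exact permutation p = 0.00724). The relation did not pass the adjustment and rests partly on KO F1 and WT F1, without which r was 0.413. B2_Mm1t and B2_Mm1a had r of 0.845 and 0.832 with PC1, and B3A 0.498.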
